A study of Mus musculus with 12 samples.

How the data were processed

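RNA from 12 mouse left ventricles, 3 in each of 4 groups, was measured on 1-colour arrays that carry probes for long noncoding and messenger RNAs. Per the labels' protocols, ribosomal RNA was removed from total RNA, and the rest was amplified by random priming along the whole transcript and labelled with Cy3. Genotype, surgery and replicate number were taken from the labels, which describe the ventricles as independent biological replicates.

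The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction 11.0.1.1 per the submitters' processing notes and the file headers, which also name background subtraction and spatial detrending within each array. Other columns are quality flags per spot (other units), per the file headers. The authors' processed values are on a log2 scale, as judged from their range and from its correlation with the log2 scanner signal of each array, which was 0.999 at its lowest. Each column of that table had a median of 6.91. The correlation per array was at least 0.9995 with quantile-normalized scanner values and 0.9988 to 0.9998 without that step, so it does not identify the method. The method is not given in the sources used here. The array's design lists mm9 as its build per the file headers, and no coordinates were used here.

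The log2 of the processed signal minus each array's 75th percentile over non-control spots was the measured value. Spots flagged as outliers were set missing (35 to 66 spots per array) and spots of 1 probe were averaged. Of 60930 probes, 52304 passed the filter on dim probes; 5 of these are negative controls by name and were left out, leaving 52299. Groups were compared with limma 3.58.1 (lmFit and eBayes, defaults) in R 4.3.3, in 1 fit over all 12 arrays with a mean per group. Called means an adjusted p under 0.05 after Benjamini-Hochberg adjustment within a comparison. Single values were compared by exact two-sided permutation tests, for which 0.1 is the smallest p with 3 arrays against 3. Figures were drawn with matplotlib 3.10.9.

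The limma fit and adjustment alone were tried on simulated normalized values for 52227 probes, with 200 changed. Noise was drawn independently for each probe, without an effect of slide or age. For MI in wild type 66% of log2 changes of 1 and 95% of changes of 2 were recovered, and 64% and 91% for MI in the knockout. For the difference of both MI effects 38% and 74% were recovered. The shares were 65% and 95% for the genotypes in sham, 68% and 88% in MI, and 86% and 96% averaged over surgeries.

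The files pair only 15 probes with transcript accessions, and all 15 were matched to symbols through a RefSeq table of assembly GRCm38.p6; each has 20 spots. The remaining probes carry design IDs that the tables used here do not pair with genes. The planned tests of gene lists and cell type markers, and the planned account of Miat, were therefore not run, and the other probe classes come from the wording of the IDs. The IDs of the 15 named probes do not say housekeeping, a name used here for the group as a whole. The planned rule for named genes was applied to the 15 genes: those called without overlap of the arrays, or, where fewer than 5 passed, those with the smallest p given as values. For unnamed probes, at most 2 that rose and 2 that fell are given per comparison, the largest changes that were well above background on all arrays of the brighter group without overlap.

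Alternatives fixed before the data were examined were quantile normalization, median centring, normexp background correction (offset 50), the authors' values, other filters, eBayes with trend and robust set, array weights, fits of only the groups compared, replicate number, age or slide as a term, a log2 minimum of 1, a plain test per probe and leaving out each array. Normexp used the median spot signal in place of the mean, and the authors' table lacked 89 of the tested probes. Slide as a random block, fits within a slide and array weights estimated gene by gene were added after the data were seen; the last because the default weights did not converge.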

Results

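Left ventricles of 12 male C57BL/6J mice were profiled 4 weeks after sham surgery or myocardial infarction (MI). The mice were wild type or lacked Miat, a long noncoding RNA, throughout the body. The 4 groups (wild-type sham, wild-type MI, knockout sham and knockout MI) held 3 independent ventricles each. Each RNA sample was labelled with Cy3 and hybridised to 1 array of 62939 spots. Between 82.6% and 88.1% of the non-control spots of an array were well above background, no non-control spot was saturated, and the number of arrays limited the precision.

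Only 15 housekeeping genes could be named among the 52299 probes tested, so the remaining 52284 are given by probe ID or by class. Miat itself was not analysed here, and the labels of the knockout arrays were therefore not checked against it. The arrays were scanned as 2 slides, and this division was not balanced over the groups. Slide 1 held all 3 wild-type MI arrays, all 3 knockout MI arrays and knockout sham replicates 2 and 3. Slide 2 held all 3 wild-type sham arrays and knockout sham replicate 1. Age did not overlap between genotypes, with wild-type mice at 13 to 14 weeks and knockout mice at 15 to 16 weeks. Knockout sham replicate 1, alone of its group on slide 2, was 16 weeks old, and replicates 2 and 3 were 15 weeks. Only these 3 arrays set the slides apart within a group, so a term for slide cannot be told apart from age. All 3 knockout MI mice were 16 weeks old, so MI against sham within slide 1 also differs in age. The first principal component held 50.1% of the variance and set the wild-type MI arrays (47.2, 65.9 and 159) apart from the other 9 arrays (-53.6 to -0.11). The probes' median SD between replicates was 0.10 on the log2 scale in wild-type sham, 0.21 in wild-type MI, 0.17 in knockout sham and 0.14 in knockout MI.

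The first comparison asked how the wild-type ventricle differed 4 weeks after infarction. Of the 15 housekeeping genes, 6 rose, 1 fell and 8 did not pass the test (limma, Benjamini-Hochberg adjustment over all probes), and adjusted over the list alone the count was also 7. Actb, a cytoskeletal actin, rose by 1.23 on the log2 scale (SE 0.21, adjusted p = 0.0069 in limma), from 4.14 ± 0.18 to 5.37 ± 0.39 (SD, n = 3 each). Ppia, which encodes the prolyl isomerase cyclophilin A, rose by 1.20 (SE 0.21), and Tuba1b, an alpha-tubulin, rose by 0.86 (SE 0.15). B2m, the light chain of MHC class I, rose by 0.98 (SE 0.27), the lysosomal enzyme gene Gusb by 0.86 (SE 0.21) and the ribosomal protein gene Rpl13a by 0.63 (SE 0.20). Gapdh, a glycolytic enzyme, fell by 0.47 (SE 0.12, adjusted p = 0.021 in limma). Separate control spots for Gapdh gave differences of -0.60 at the 3′ probe and -0.64 at the 5′ probe, each with an exact two-sided permutation p = 0.1, the smallest that 3 arrays against 3 can give.

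Across the array, 13938 probes were called at an adjusted p under 0.05 in limma, 6700 higher and 7238 lower after infarction; a plain test per probe with equal variance called 0 after adjustment. The balance of higher and lower calls was not stable, with 5614 and 9024 under quantile normalization, 5630 and 8958 in the authors' values and 7845 and 6002 under normexp. It also turned in a fit of these 2 groups alone (5001 higher and 3989 lower), without wild-type sham replicates 1 (2556 and 2144), 2 (2414 and 1620) or 3 (4583 and 3889), and without wild-type MI replicate 2 (3471 and 3278). In group mean, probe ASMM10P053276 was at least 25.7-fold higher and probe ASMM10P001257 at least 14.7-fold higher. Neither was well above background on any wild-type sham array. Such a lower bound sets the bright group's mean against the dim group's limit of detection. Wild-type MI replicates 1, 2 and 3 lay at 1.61, -1.94 and 1.32 for the first probe and 0.84, -2.99 and 0.72 for the second. Replicate 2 alone falls short of both bounds. Probe ASMM10P046283 fell by 6.42 (SE 0.48) and probe ASMM10P042837 by 6.35, from 3.82 ± 1.39 to -2.53 ± 2.35 (SD, n = 3 each). Probes named for long intergenic noncoding RNAs fell more often than they rose: 170 of 816 human-named probes were lower and 52 higher, against 99 lower and 28 higher of 480 mouse-named probes. Among the 69 lincRNA exon probes, 13 were lower and 4 higher, while the large ASMM class gave 6955 lower and 6610 higher. The 3 lincRNA classes together also held more lower than higher calls under quantile normalization (326 and 70), median centring (279 and 86), normexp (211 and 98) and the authors' values (324 and 70). Every wild-type sham array lay on slide 2 and every wild-type MI array on slide 1, so no value within a slide could be had; with slide as a block, resting on knockout sham replicate 1, 5490 probes were called, and Tuba1b, B2m (which with Rpl13a also did not pass under quantile normalization or in the authors' values), ASMM10P053276, ASMM10P001257 and ASMM10P042837 did not pass. The count was 4700, 4034 and 8472 without wild-type sham replicates 1, 2 and 3, 6749 without wild-type MI replicate 2, 8990 in a fit of these 2 groups alone and 24254 with array weights estimated gene by gene; without wild-type MI replicate 2 B2m, Gapdh and Rpl13a did not pass, and B2m, Gapdh, Gusb and Rpl13a did not without wild-type sham replicate 1 or 2, nor Gapdh and Rpl13a without replicate 3, nor Rpl13a without wild-type MI replicate 3.

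**Figure D1:**
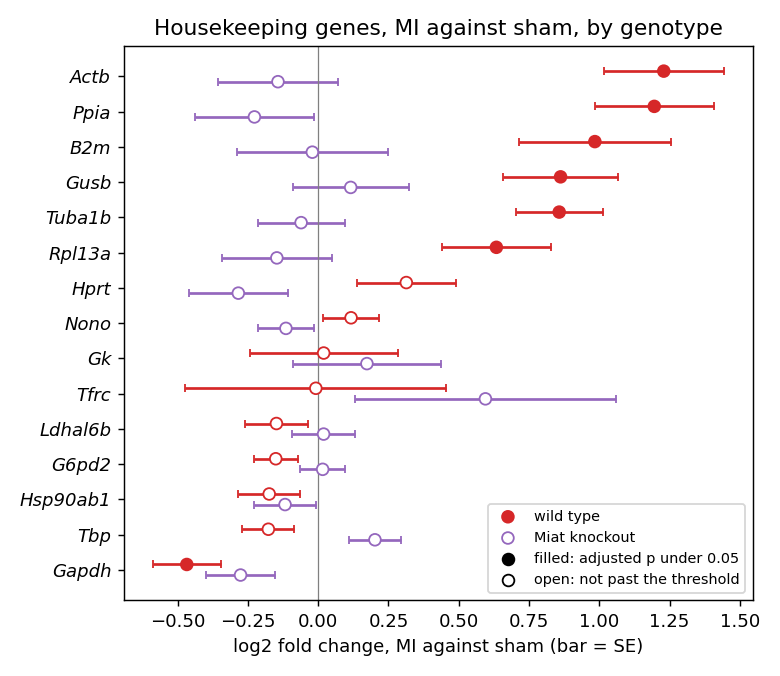
Log2 fold change of the 15 housekeeping genes between MI and sham (horizontal axis, bars are SE) in wild-type and Miat knockout ventricles, 3 arrays per group, with filled points past an adjusted p of 0.05 in limma. In wild type 7 points are filled, from Gapdh at -0.47 to Actb at 1.23, and in the knockout 0 are.

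The same surgery was then compared in the Miat knockout. None of the 15 housekeeping genes passed the test, whether adjusted over all probes or adjusted over the list alone (0 in both cases), and 1 had an unadjusted p under 0.05. The 6 with the smallest p had log2 differences of -0.28 for Gapdh (SE 0.12), 0.20 for Tbp (SE 0.09), -0.28 for Hprt (SE 0.18), 0.59 for Tfrc (SE 0.46), -0.11 for Nono (SE 0.10) and -0.23 for Ppia (SE 0.21). Probes of the lincRNA-named classes gave 0 calls in either direction. Over all 52299 probes limma called 0 at a smallest adjusted p of 0.41, with 4893 probes at an unadjusted p under 0.05 where 2615 were due by chance. A plain test per probe with equal variance called 0 after adjustment, as it did in wild type, so it did not separate the genotypes. The authors' values and a fit of the 2 groups alone called 1 each. The 0 did not hold with array weights: 4346 probes were called with weights estimated gene by gene, which ranged from 0.16 to 8.35, and 11078 with default weights that did not converge. Within slide 1, with 3 MI and 2 sham arrays, 0 probes were called, and 2 were called without knockout MI replicate 1.

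The response of the probes called in wild type was followed on every array as the mean of the higher probes minus the mean of the lower ones, relative to wild-type sham. The shift was 1.56 ± 0.48 in wild-type MI, 0.32 ± 0.23 in knockout MI, 0.18 ± 0.14 in knockout sham and 0.00 ± 0.12 in wild-type sham (SD, n = 3 each). The knockout difference between MI and sham was 0.13, or 8.51% of that in wild type, with an exact two-sided permutation p = 0.4, where 0.1 is the smallest possible. These probes were chosen on the wild-type arrays, which enlarges the wild-type value; arrays left out of the choice gave 1.27, 2.30 and 0.94 for wild-type MI between 0.04 and 0.59 for knockout MI, between 0.03 and 0.33 for knockout sham, and -0.01, 0.05 and 0.34 for wild-type sham, of which the last lies within the knockout MI range. Probes that rose in wild type had a median change of 0.84 there and 0.08 in the knockout, and probes that fell had medians of -0.53 and -0.01. From knockout sham to knockout MI, ASMM10P053276 went from -4.37 ± 0.19 to -2.39 ± 1.58 (SD, n = 3 each). ASMM10P001257, not well above background on any knockout sham array, went from -5.04 ± 0.51 to -3.29 ± 1.99. ASMM10P046283 and ASMM10P042837, which fell in wild type, went from -1.13 to -0.74 and from -3.50 to -3.30. With 0 calls in the knockout no call could be shared. Of 2908 wild-type calls over 2-fold, 263 had an unadjusted p under 0.05 in the same direction in the knockout. Among all 52299 probes, 4893 had such a p in the knockout, but in either direction, so the 2 counts cannot be compared directly. Of the probes called higher in wild type, 60.5% also lay above 0 in the knockout. Of those called lower, 51.5% lay below 0. The fold changes correlated across probes, which are not independent replicates, with Pearson's r = 0.24 and Spearman's rho = 0.13. Pearson's r lay between 0.10 and 0.37 when single arrays were left out. With slide as a block it was 0.48, but both effects are then taken against knockout sham replicates 2 and 3, and 20 simulations with no change in any group gave a mean r of 0.37 (covariance 0.0370, against 0.119 observed).

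**Figure D2:**
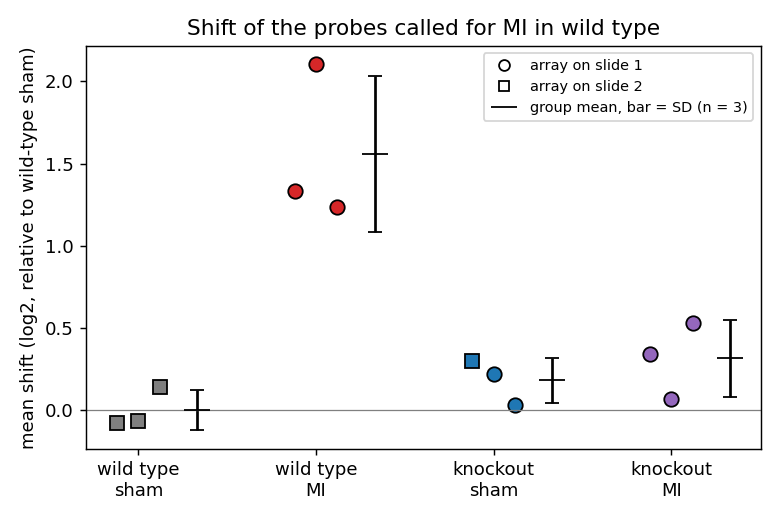
Mean shift on the log2 scale, relative to wild-type sham, of the probes called for MI in wild type, for each array by group, with circles for slide 1, squares for slide 2, and group means with SD (n = 3). The wild-type MI arrays lie between 1.23 and 2.10, and the knockout MI arrays between 0.07 and 0.53.

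Whether the response to infarction differed between genotypes was tested as the difference of both MI effects. Of the 15 housekeeping genes, 3 had a smaller MI effect in the knockout and 12 did not pass, and adjusted over the list alone the count was also 3. The differences were -1.37 for Actb (SE 0.30, adjusted p = 0.042 in limma), -1.42 for Ppia (SE 0.30, adjusted p = 0.038) and -0.92 for Tuba1b (SE 0.22, adjusted p = 0.047). Values that did not pass were -1.01 for B2m (SE 0.38), -0.78 for Rpl13a (SE 0.28) and 0.38 for Tbp (SE 0.13). Among 1961 probes called in limma with Benjamini-Hochberg adjustment, 842 differences were positive and 1119 negative. The leading positive differences were 6.80 for ASMM10P046283 (SE 0.67) and 6.55 for ASMM10P042837 (SE 1.42), and a negative one was -3.75 for ASMM10P054189 (SE 0.65). ASMM10P009732 was also called as negative, but was not well above background on any of the 6 knockout arrays and on only 1 of 3 wild-type sham arrays, so its fitted difference was not read as a size. The direction of the calls was not stable, with 572 positive and 333 negative under quantile normalization, 583 and 340 in the authors' values, 684 and 1433 under median centring and 1178 and 3309 under normexp, and Actb, Ppia and Tuba1b did not pass under quantile normalization or in the authors' values, nor did ASMM10P042837 under quantile normalization, nor Tuba1b and ASMM10P042837 with slide as a block. The count fell to 0 without knockout sham replicate 2, 1 without knockout MI replicate 2, 1 without wild-type sham replicate 1, 5 without knockout MI replicate 1, 53 and 391 without wild-type sham replicates 2 and 3 and 1244 without wild-type MI replicate 2, and also fell to 0 with age as a covariate. It was 3143 without knockout sham replicate 3 (1711 positive and 1432 negative), 4504 with slide as a block (2512 and 1992) and 13505 with gene-by-gene array weights. With slide as a block, the knockout sham value in this difference came from replicate 1 alone.

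Between the genotypes after infarction, 5 of the 15 housekeeping genes were lower in the knockout, 10 did not pass, and adjusted over the list alone the count was also 5. Ppia was lower by a log2 difference of -1.01 (SE 0.21, adjusted p = 0.016 in limma), Actb by -0.86 (SE 0.21), Tuba1b by -0.71 (SE 0.15) and Gusb by -0.74 (SE 0.21). B2m had a difference of -0.92 (SE 0.27, adjusted p = 0.035 in limma) with overlapping arrays, and Rpl13a did not pass at -0.52 (SE 0.20). Probe ASMM10P041158 was higher in the knockout by 3.28 (SE 0.36) and probe ASMM10P041157 by 2.96 (SE 0.27). Probe ASMM10P054189 was lower, at -2.68 ± 0.13 in the knockout and 3.03 ± 0.82 in wild type (SD, n = 3 each), and probe ASMM10P053763 was at least 9.78-fold lower. The 3 lincRNA-named classes together gave 308 higher and 40 lower calls of 1365 probes, with more higher than lower calls in each of the 4 other scalings. This comparison uses the same wild-type MI arrays as the first one, so opposite directions in both are partly built in.

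In all, limma called 12581 probes after Benjamini-Hochberg adjustment, 6611 higher and 5970 lower in the knockout. The balance turned under median centring (5469 higher and 6561 lower) and normexp (5194 and 6445), and in a fit of these 2 groups alone, with 29 higher and 312 lower. It turned as well within slide 1 (2710 and 3349) and without knockout MI replicates 2 (231 and 754) or 3 (3775 and 4213) or wild-type MI replicate 2 (1938 and 2094). All 6 arrays were on slide 1, and a fit of the slide 1 arrays alone called 6059, without Gusb and B2m, and under quantile normalization and in the authors' values Actb, B2m and Tuba1b did not pass, nor did Ppia in the authors' values. The count was 3780, 985 and 7988 without knockout MI replicates 1, 2 and 3, 4032 without wild-type MI replicate 2 (Actb, B2m and Gusb did not pass without this array or knockout MI replicate 1 or 2, nor Tuba1b without either of the latter, nor Ppia without the last) and 341 in a fit of these 2 groups alone, and 0 with age as a covariate, which is joined to genotype.

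**Figure D3:**
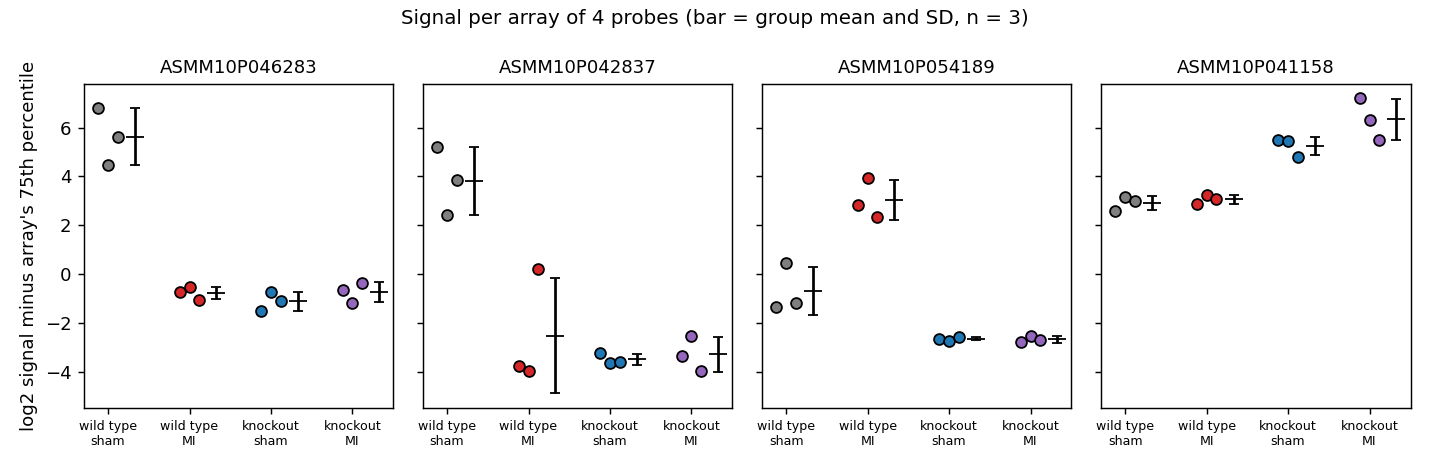
Log2 signal minus the array's 75th percentile (vertical axis) of 4 probes on each array by group, with group means and SD (n = 3). ASMM10P046283 and ASMM10P042837 are brightest in wild-type sham (means 5.64 and 3.82), ASMM10P054189 in wild-type MI (3.03), and ASMM10P041158 in the knockout groups (5.24 in sham and 6.34 in MI).

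After sham surgery none of the 15 housekeeping genes passed between the genotypes in limma, and adjusted over the list alone the count was also 0. Of these genes, 2 had an unadjusted p under 0.05, and the smallest p belonged to Tbp, at -0.26 (SE 0.09), and Actb, at 0.52 (SE 0.21). Ppia had a difference of 0.41 (SE 0.21), Rpl13a 0.26 (SE 0.20), Tuba1b 0.20 (SE 0.15) and Hsp90ab1 -0.14 (SE 0.11). Probe ASMM10P046283 was lower in the knockout, at -1.13 ± 0.39 against 5.64 ± 1.18 in wild type, and probe ASMM10P042837 was lower at -3.50 ± 0.22 against 3.82 ± 1.39 (SD, n = 3 each). Probes ASMM10P045345 and ASMM10P012959 were higher, at least 1.31-fold and at least 1.5-fold, and were not well above background on any wild-type sham array. Altogether 21 probes passed limma with Benjamini-Hochberg adjustment, 14 higher and 7 lower, against 17 higher and 5 lower under median centring and 235 higher and 32 lower under normexp. Quantile normalization and the authors' values gave 4 higher and 2 lower each, and ASMM10P042837 did not pass in either (adjusted p = 0.053 and 0.056 in limma, over a range of 2.5e-05 to 0.67 across its alternatives). Within slide 2 the knockout was 1 array, so the count of that fit is not read as a genotype difference. The count was 2600 with slide as a block (1155 higher and 1445 lower), which again sets only knockout sham replicate 1 against wild-type sham. With age as a covariate the count was 0, and with gene-by-gene array weights 14559. It was 117, 1 and 1 without knockout sham replicates 1, 2 and 3, and 2 without any 1 of the wild-type sham arrays.

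Averaged over both surgeries, none of the 15 housekeeping genes passed in limma between knockout and wild type, and adjusted over the list alone the count was also 0; 2 had an unadjusted p under 0.05. The values were -0.36 for Gusb (SE 0.15), -0.25 for Tuba1b (SE 0.11), -0.42 for B2m (SE 0.19), -0.30 for Ppia (SE 0.15), 0.34 for Gk (SE 0.19) and 0.14 for Gapdh (SE 0.09). Probe ASMM10P041158 was higher in the knockout by 2.80 (SE 0.25) and probe ASMM10P041157 by 2.33 (SE 0.19). Probe ASMM10P054189 had a difference of -3.83 (SE 0.33) and probe ASMM10P050522 of -2.93 (SE 0.35). The lincRNA-named classes gave 179 higher and 24 lower calls, and all classes together 7031 probes in limma with Benjamini-Hochberg adjustment, 3657 higher and 3374 lower. The balance turned with slide as a block (3740 higher and 3851 lower) and without knockout MI replicates 2 or 3, knockout sham replicate 2 or wild-type sham replicates 1 or 3 (1617 and 2047 without wild-type sham replicate 1). The slide block again took the knockout sham value from replicate 1 alone. With age as a covariate 0 probes passed, and gene-by-gene array weights gave 16122. The count was 3322, 2072 and 3698 without knockout MI replicates 1, 2 and 3, 4605, 3177 and 4374 without knockout sham replicates 1, 2 and 3, 3664, 2463 and 1064 without wild-type sham replicates 1, 2 and 3, and 11784 without wild-type MI replicate 3.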

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

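The tests of slide, of single arrays and of a wrong label for infarction in wild type and knockout, and that of slide for the probes bright in wild-type sham, were chosen after the results were seen.

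The MI effect differed between genotypes for 1961 probes, and among named items for Actb (-1.37), Ppia (-1.42), Tuba1b (-0.92), ASMM10P046283 (6.80), ASMM10P042837 (6.55), ASMM10P054189 (-3.75) and ASMM10P009732 (-4.41), all on the log2 scale and tested as an interaction. The value for ASMM10P009732 is a fitted one with no meaning as a size, because the probe was not well above background on the 6 knockout arrays. With age as a covariate the count was 0. Of 100 assignments of genotype within each surgery, the real one included, 1 gave as many probes, and the highest of the others gave 549. Such redraws test for no genotype difference of any kind, so they cannot decide on the interaction alone. They also ignore slide, which differed between the genotypes in sham, and genotype and age remain joined. The averaged comparison of genotypes gave 7031 probes against a highest other count of 182, with 1 of 100 as large. Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05: the real split gave 13938 probes for MI in wild type against a highest other count of 0, 12581 for the genotypes in MI against 0, and 21 for the genotypes in sham against 2, in each case 1 split of 10. For MI in the knockout all 10 splits gave 0.

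Infarction gave 13938 calls in wild type and 0 in the knockout in limma, whereas a plain test per probe gave 0 in both. Slide as the whole cause is argued against by knockout sham replicates 2 and 3, which were on the slide of the wild-type MI arrays and whose mean shift was 8.01% of the wild-type difference. Slide as part of the wild-type count cannot be told apart from surgery, because no slide holds both wild-type groups, and 5490 calls were made with slide as a block. Wild-type MI replicate 2 alone does not account for the calls, since 6749 were made without it, and 1 wrongly labelled knockout MI array does not either, since the highest of the 3 shifts was 0.53, below every wild-type MI array. Genotype and age stay open, joined as they are (with age as a covariate, 10118 calls in wild type and 0 for the difference), the extent of the infarcts was not tested, and the 0 in the knockout became 4346 with gene-by-gene array weights.

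ASMM10P046283 and ASMM10P042837 were brightest on the wild-type sham arrays. A local defect of the surface is argued against by the 11 and 12 probes around them, with a median difference between wild-type sham and the other arrays of 0.19 or less. Slide is argued against by knockout sham replicate 1, from the same slide, which lay at least 5.66 below the lowest wild-type sham array. What these probes detect, and whether genotype or other tissue in the samples is involved, stays open.

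Probes meant as negative controls by name gave signal in data that no comparison used. After MI in wild type the mean log2 signal was 1.54 for MM9NEGATIVE008, -3.34 for MM9NEGATIVE017 and -3.17 for MM9NEGATIVE016, on every array above the wild-type sham arrays, whose means were 0.35, -3.55 and -3.47.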

How the results depend on the processing

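Slide as a random block, fits within a slide, gene-by-gene array weights, the correlation without single arrays and its simulation were chosen after the data were seen; the other alternatives were fixed before. Counts are given for MI in wild type, MI in the knockout, the genotypes in sham, the genotypes in MI, the difference of MI effects and the averaged genotypes, in that order where all are listed; the values before any change are 13938, 0, 21, 12581, 1961 and 7031. Unless stated, the cause was not tested. Quantile normalization gave 6 in sham and 905 for the difference, normexp 267 and 4487, the authors' values 6 and 923 (and 1 for MI in the knockout), no filter 10 and 784, and probes above background on all 12 arrays 11 in sham. Default array weights gave 33654, 11078, 23609, 24065, 22247 and 23416; they did not converge and put a weight of 671.8 on knockout sham replicate 2. Gene-by-gene weights, at most 8.35 and also highest on that array, gave 24254, 4346, 14559, 13505 for the difference and 16122 for the average. Fits of the groups compared alone, with fewer arrays behind the spread, gave 8990, 1, 0 and 341. Age gave 0 in sham, in MI and for the average, where it is joined to genotype, and 0 for the difference. Tuba1b between genotypes in MI then turned to 0.0911 (SE 0.29, adjusted p = 0.97 in limma), which cannot be told from no difference. Slide as a fixed block gave 5490 for MI in wild type, 2600 in sham, 4504 for the difference and a correlation of both MI effects of 0.48, against 0.37 in simulations with no change, from shared arrays. Its counts in sham and for the difference took the knockout sham value from replicate 1 alone. As a random block, slide gave 5671 for MI in wild type and 2 in sham. On slide 2 the knockout was replicate 1 alone, so a fit of that slide has no spread between knockout mice. Its count in sham is listed for completeness and is not read as a genotype difference. Slide 1 alone gave 6059 for the genotypes in MI and slide 2 alone 5365 in sham. A log2 minimum of 1 gave, by its construction, 2908, 11, 2106, 1045 and 436 without the knockout MI comparison, and a plain test per probe 0 for MI in wild type, 1 in sham and 3 in MI.

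Leaving out single arrays moved the counts between 4034 and 17764, 0 and 2, 1 and 117, 985 and 16422, 0 and 3143, and 1064 and 11784, and the correlation between 0.0997 and 0.373. Of the checks of these counts and the correlation under an alternative, 85 moved and 75 did not. A count moved if it changed by more than 1.5-fold or to or from 0. Each named gene or probe, those given only as values included, was also checked under each alternative that covered it. In 762 such checks it kept direction and side of the threshold, or turned by under 1 SE without being called in either fit. Without turning, it lost its call in 150 and gained one in 24. It turned by more in 7 with no call in either fit, and in 1 with a call.

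With the replicate number as a block the counts were 2 in sham, 102 for the difference and 4420 for the average; 6 of 18 pairs of same-numbered arrays correlated above 0.1 (from -0.34 to 0.34), so the numbers were not taken to pair the arrays. The gene list, cell type and Miat alternatives were not run, because the probes could not be named here. Signal over background limits the dim probes. Changes between groups are given as bounds where 1 group was not well above background, and no bound was computed for differences of effects.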

Other observations

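The test of consecutive probe numbers was chosen after part of the result was seen.

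The lincRNA-named probes gave 282 lower and 84 higher calls for MI in wild type, of 1365 tested. They were dimmer than the ASMM class, with median log2 signals of -2.11 and -1.31. Brightness of the probes may produce such an excess, but of 10000 sets of ASMM probes matched on brightness 0% held as many lower calls. The sets ranged from 124 to 224. They treat probes as independent, but all probes share the same arrays, so this range may be too narrow. Slide as the only cause is argued against by the MI arrays, all on slide 1. There 308 of these probes were higher and 40 lower in the knockout, in a comparison that uses the same wild-type MI arrays. Knockout sham, mostly on slide 1, had class medians of 0.04 (human-named), 0.05 (mouse-named) and 0.07 (exon) above wild-type sham. A part played by slide, which is joined to surgery in wild type, and any shared biology of these transcripts remain open.

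ASMM probes with consecutive numbers may stand for related transcripts. Their MI changes in wild type correlated with r = 0.0523 over 44203 pairs of probes, against at most 0.0136 in 1000 shuffles of the numbers. The correlation is across probes, which are not independent replicates, and is small.

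The control probes MM9NEGATIVE002 and MM9NEGATIVE003 had log2 signals of -1.86 ± 0.23 and -1.70 ± 0.21 in wild-type sham and -2.50 ± 0.50 and -2.29 ± 0.49 in wild-type MI (SD, n = 3 each).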
